A study of Homo sapiens with 6 samples.

How the data were processed

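Human bone marrow mesenchymal stem cells had been transduced with a retroviral vector carrying TWIST1 or with the empty vector, and polyadenylated RNA was sequenced from 3 libraries per group, made with a strand-preserving kit per the labels' protocols. Groups and replicate numbers were taken from the sample titles. The deposited values were whole-number counts per transcript, not normalized. The submitters' processing notes name cutadapt (a read trimmer), HISAT2 (an aligner), featureCounts (a read counter) and genome build hg19 for these deposited counts. The versions, the order of steps, the annotation release, the strand setting and the treatment of reads shared between transcripts are not given in the sources used here. Each table listed the same 204940 transcripts with a length and a count, and the lengths were used only to check for a length effect.

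The tables give transcript identifiers and no gene names. Names were taken by identifier from GENCODE release 29, which is on another genome build than hg19, so no coordinates are given. Of the transcripts, 181859 matched and were summed to 52994 genes, and 23081 did not match. The unmatched transcripts held 1.49% to 1.54% of a library's counts and stayed out of library sizes and of the main test. After the sum a library held 8824266 to 10592793 counts. Some genes known to be abundant held few counts, with GAPDH between 84 and 124 counts per library over 10 transcripts and VIM between 177 and 348 over 9. Not every gene with as many transcripts held so few counts, as COL12A1 with 10 held 953 to 4231 counts per library. Of these counts 99.9% lay on coding transcripts, which does not show whether shared reads were lost there too. Few counts would arise if reads that fit more than 1 transcript of a gene were left uncounted, so levels cannot be compared between genes with different numbers of isoforms, and a change of isoform can change a gene's value. Paralogs and overlapping genes can share reads in the same way, and antisense partners can too where strand was not used.

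Genes were tested with edgeR 4.0.16 in R 4.3.3 by the quasi-likelihood test with robust estimation, TMM scaling and the default filter by group, which asks for about 10 counts at the median library size in at least 3 libraries and 15 counts in all. The test is two-sided, p-values were adjusted by Benjamini-Hochberg over all 11293 tested genes, and genes with an adjusted p below 0.05 were called. Standard errors were the size of the log2 fold change divided by the square root of the F statistic. Levels are CPM, counts scaled to the library size after TMM scaling and not to the plain sum of gene counts, with the SD over 3 libraries. Where a group had no count, the fold was bounded with a floor of 3 counts over the group. Where it had 1 to 3 counts, the ratio is given with an exact 95% interval, and such intervals cover counting error only. The biological coefficient of variation was 7.62%. Counts of replicates within a group differed by more than sampling noise, with a chi-square per degree of freedom of 2.04 to 7.57, so none was treated as a duplicate.

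The test, the alternatives, 29 gene lists of 586 symbols and the rule for named genes were fixed before the data were examined. Of the symbols 584 matched. Lists with at least 5 tested members were tested with camera at an inter-gene correlation of 0.01 and adjusted over the 27 tested lists, and again with an estimated correlation and with fry from limma 3.58.1, whose directional p asks whether a list's genes move on balance one way. The genes named are 12 fixed individually; the 8 largest rises and the 8 largest falls among called genes with at least 5 CPM in the higher group and no overlap between groups, without XIST, Y-linked genes and loci without a symbol of their own; up to 3 called members of each list with the largest change, or at most 2 of those highest in CPM where none was called; and the 4 called genes highest in CPM with at least a 2-fold change. The values of 1 gene taken by this rule are not reported here. Other list members that the text names were chosen after their values were seen. A further 8 lists were drawn up after the data had been seen and appear only in the closing observations.

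On simulated counts for the genes of this comparison, 200 genes with a mean above 2 CPM were changed. Among them edgeR recovered 68.7% of genes changed 1.5-fold, 89.6% of those changed 2-fold and 100% of those changed 4-fold, and 6.5% of its calls were false. The simulated spread of each gene followed the trend with level, so genes that vary more than the trend are not covered. With 2898 genes called in the data against 200 changed here, the recovered and false shares may not carry over. Of 200 unchanged simulated lists, camera gave p below 0.05 for 3.5%. Genes were simulated independently and these lists were drawn at random, so this share does not cover lists whose genes are correlated. Alternatives were DESeq2 1.42.0, limma-voom, RLE, upper-quartile and total-count scaling, no filter and another filter on low counts, the replicate number as a block, robust estimation off, each library left out in turn and other list tests. Coding transcripts only, and all genes without those encoded in mitochondria, were alternatives added after seeing the data. With coding transcripts only, protein-coding genes kept the counts of their coding transcripts, and all other genes kept their counts in full. Figures were drawn with matplotlib 3.10.9.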

Results

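Polyadenylated RNA was sequenced from human mesenchymal stem cells, the adherent stromal progenitors of bone marrow, after transduction with a retroviral vector carrying TWIST1 or with the empty vector. TWIST1 is a basic helix-loop-helix transcription factor of mesoderm development. There were 3 libraries in each of the 2 groups, 6 in all, named by the labels as biological replicates. The deposited tables held between 8959214 and 10758715 counts per library. In the TWIST1 group replicates 1, 2 and 3 held 9055174, 8959214 and 9524635 counts, and in the empty-vector group 10758715, 9405601 and 10220681. The single comparison the design implies asked which transcripts differed in abundance between TWIST1-overexpressing and empty-vector cells. The labels do not say whether replicates came from separate donors, cultures or transductions, so the p-values measure the spread between these libraries, which may be technical.

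TWIST1 itself was measured at 1768, 1494 and 1476 CPM in the TWIST1 libraries and at 38.5, 45.6 and 47.1 CPM in the empty-vector libraries. CPM are counts scaled to the library size after TMM scaling. The group means were 1579 ± 164 CPM (SD, n = 3) and 43.7 ± 4.61 CPM (SD, n = 3), a log2 fold change of 5.18 (SE 0.13, edgeR quasi-likelihood adjusted p = 1.05e-05). The count includes transcripts of the introduced cDNA as far as the gene model covers it, so the level of the endogenous gene in the transduced cells was not separable. TWIST2, the closest relative of TWIST1, stood at 4.19 ± 0.85 CPM against 6.99 ± 3.07 CPM (SD, n = 3) and was not called (log2 fold change -0.73, edgeR adjusted p = 0.103). Without empty-vector replicate 1 it was called, with a log2 fold change of -1.05 and an edgeR adjusted p of 0.000549, and with all 6 libraries and no filter on low counts it was called with a log2 fold change of -0.73 and an adjusted p of 0.0210.

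**Figure D1:**
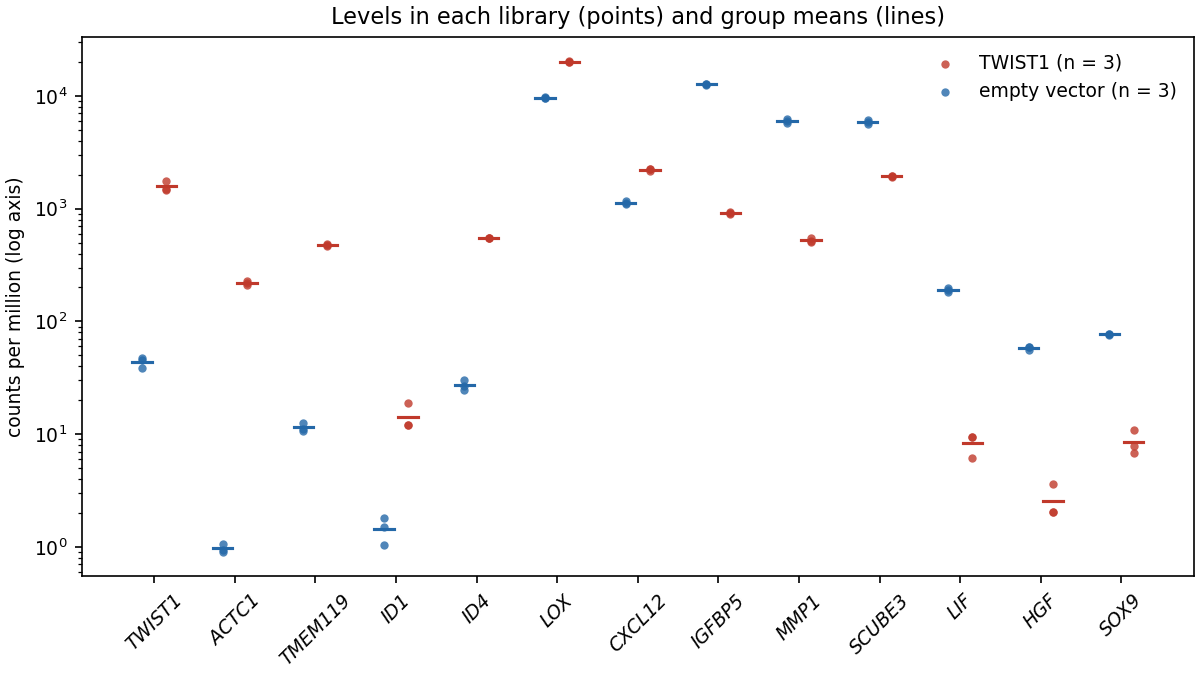
CPM on a log axis for 13 named genes, with each library as a point and each group mean as a line, red for TWIST1 and blue for the empty vector (n = 3 each). The 3 TWIST1 libraries hold TWIST1 at 1476 to 1768 CPM and the 3 empty-vector libraries at 38.5 to 47.1 CPM.

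Of 11293 genes tested, 1269 rose and 1629 fell with TWIST1, which together is 25.7% of those tested. Changes of at least 2-fold were found for 389 genes that rose and 528 that fell, and the median log2 fold change of all tested genes was 0.01. Of the genes that changed at least 2-fold, 4 are named for their level in CPM as counted. LOX, which crosslinks collagen and elastin, rose from 9644 ± 56.1 to 20157 ± 135 CPM (SD, n = 3). IGFBP5, a secreted binding protein of insulin-like growth factors, fell from 12649 ± 169 to 919 ± 16.5 CPM. The interstitial collagenase MMP1 fell from 5989 ± 272 to 524 ± 22.1 CPM, and the secreted glycoprotein SCUBE3 fell from 5881 ± 244 to 1934 ± 27.4 CPM. The 3 libraries of one group lay wholly above those of the other for 4177 genes, 37% of those tested where chance gives 10%, and 2806 of these were called.

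Besides TWIST1, the 7 protein-coding genes with the largest rises, among those with at least 5 CPM in the higher group, were the following. MXRA5, a matrix remodelling protein, rose from 0.063 ± 0.109 to 110 ± 5.55 CPM (SD, n = 3), a ratio of 1643 with a 95% counting interval of 454 to 13572. The carboxypeptidase-like gene CPXM2 had no count in the empty-vector libraries and was at least 58.7-fold higher with TWIST1, with 3 counts over the group as the floor. Cardiac alpha-actin, ACTC1, rose from 0.973 ± 0.086 to 220 ± 9.40 CPM, a log2 fold change of 7.80 (SE 0.11). Dermatopontin, DPT, rose with a ratio of 107 (95% counting interval 29.2 to 889). The potassium channel gene KCND3, TMEM119 and PI16 rose with log2 fold changes of 6.26 (SE 0.19), 5.37 (SE 0.06) and 4.84 (SE 0.18). For MXRA5 and DPT all counts in the empty-vector group, 2 each, lay in replicates 1 and 3, and without that library the fitted log2 fold changes went from 10.4 to 13.0 and from 6.48 to 9.07. The edgeR adjusted p of these 7 genes beside TWIST1 lay at or below 1.49e-12.

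By the same rule the 8 largest falls were the following. The small GTPase gene RAB27B fell with a ratio of 388 (95% counting interval 69.3 to 15362), and the secreted WNT antagonist SFRP1 with a ratio of 102 (27.9 to 847). GDF6, a ligand of the BMP family, fell from 120 ± 2.18 to 2.53 ± 0.76 CPM (SD, n = 3), a log2 fold change of -5.56 (SE 0.12). The EGF receptor ligand EREG fell from 7.71 ± 1.61 to 0.147 ± 0.128 CPM. The log2 fold changes of NPTX1, LYPD1, EPHA3 and PCLO were -5.72 (SE 0.18), -5.59 (SE 0.17), -5.30 (SE 0.49) and -5.20 (SE 0.41). For RAB27B, SFRP1 and EPHA3 all counts in the TWIST1 group, 1, 2 and 4, lay in replicates 1, 3 and 1. Without that library the fitted log2 fold changes went from -8.16 to -10.1 (-7.49 with limma-voom), from -6.45 to -9.17 and from -5.30 to -8.93. The edgeR adjusted p of these 8 genes lay at or below 7.70e-11.

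**Figure D2:**
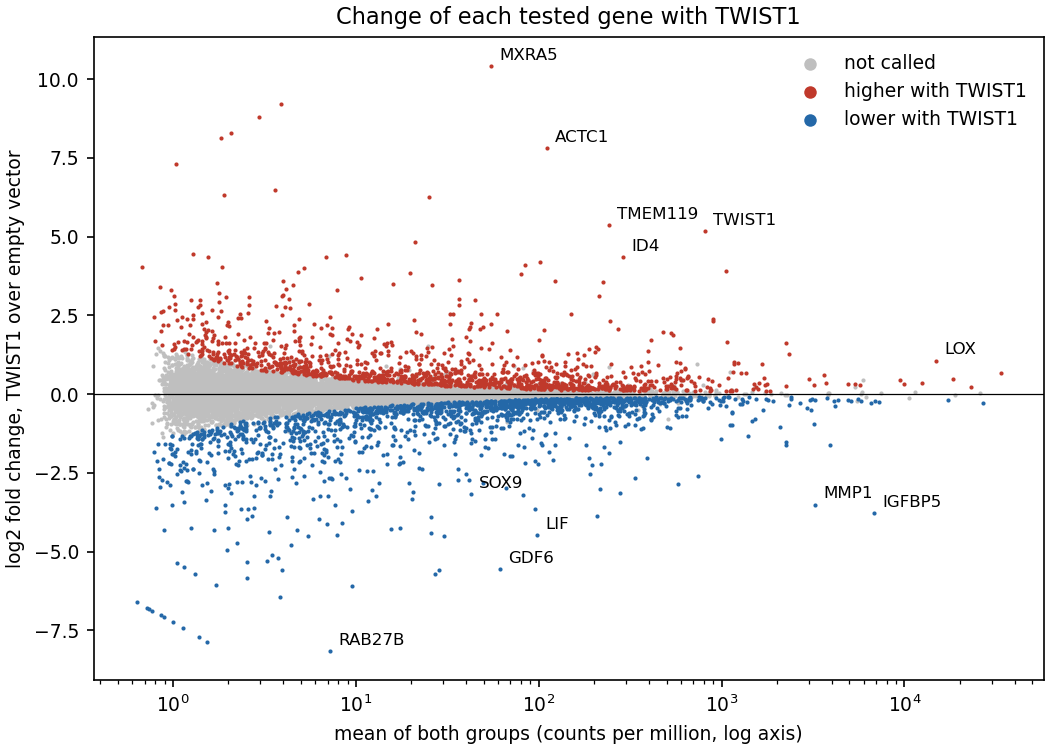
Log2 fold change of tested genes against the mean of both groups in CPM (log axis), with genes called higher in red, called lower in blue and the rest in grey. XIST, TSIX and Y-linked genes were not drawn. Any of them that were tested count among the 11293 genes tested, 1269 called higher and 1629 called lower. Fitted values of genes at 0 in one group depend on the prior count and are not bounds.

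Senescence-associated secretory factors, proteins that senescent cells release, were lower as a list (camera adjusted p = 8.75e-28, adjusted p = 0.0539 with an estimated correlation). Of its 9 tested members 7 fell, 0 rose and 2 were not called, and the counts were the same adjusted over the list alone. The other 13 of its 22 members had too few counts to be tested. Besides IGFBP5 and MMP1, the inflammatory cytokine IL1B fell from 9.11 ± 0.71 to 0.441 ± 0.286 CPM (SD, n = 3), a log2 fold change of -4.32 (SE 0.34). Haematopoietic support factors, which marrow stroma supplies to blood progenitors, were lower as a list (camera adjusted p = 3.11e-06, adjusted p = 0.0539 with an estimated correlation). Here 5 of 10 tested members fell, 2 rose and 3 were not called, with 3 rising when adjusted over the list alone. HGF fell from 58.3 ± 2.39 to 2.57 ± 0.92 CPM, LIF from 188 ± 7.79 to 8.36 ± 1.93 CPM and JAG1 from 154 ± 9.56 to 64.8 ± 2.47 CPM. CXCL12, the chemokine that retains haematopoietic stem cells in marrow, went the other way and rose from 1128 ± 31.2 to 2205 ± 49.4 CPM (log2 fold change 0.97, SE 0.03, edgeR adjusted p = 5.38e-24). With limma-voom in place of edgeR the list of support factors was not called (adjusted p = 0.238).

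The list of bHLH partners and inhibitors of TWIST1 was higher (camera adjusted p = 6.70e-10, adjusted p = 0.0539 with an estimated correlation). Of 7 tested members 4 rose, 0 fell and 3 were not called, also when adjusted over the list alone. The 4 were ID1 to ID4, which bind bHLH proteins and keep them from DNA. ID4 rose from 27.1 ± 2.83 to 549 ± 4.18 CPM (SD, n = 3), ID1 from 1.45 ± 0.39 to 14.3 ± 3.96 CPM and ID2 from 0.30 ± 0.09 to 2.49 ± 0.31 CPM. The partners TCF4 and TCF12 were not called, with log2 fold changes of -0.64 and 0.10.

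The list of epithelial-mesenchymal transition regulators and mesenchymal genes was higher (camera adjusted p = 0.00534, adjusted p = 0.203 with an estimated correlation), with 5 of 13 tested members rising, 2 falling and 6 not called, and 6 rising and 3 falling adjusted over the list alone. SNAI1, a transcriptional repressor of epithelial genes, rose from 43.9 ± 6.51 to 255 ± 6.56 CPM (SD, n = 3). The mesenchymal transcription factor PRRX1 rose from 766 ± 18.3 to 1562 ± 35.8 CPM and the cadherin CDH11 from 4.25 ± 1.27 to 11.1 ± 1.15 CPM. SNAI2, a relative of SNAI1, had too few counts to be tested (0.898 ± 0.600 against 0.266 ± 0.046 CPM). Of 6 tested epithelial genes 3 fell and 1 rose (camera adjusted p = 0.478). Those that fell were the tight junction gene CLDN1, with a ratio of 44.5 (95% counting interval 14.9 to 218), KRT18 and KRT19. All 3 counts of CLDN1 in the TWIST1 group lay in replicate 2, without which its fitted log2 fold change went from -5.32 to -8.58. The desmosome gene DSP rose from 581 ± 21.0 to 777 ± 17.6 CPM (SD, n = 3).

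**Figure D3:**
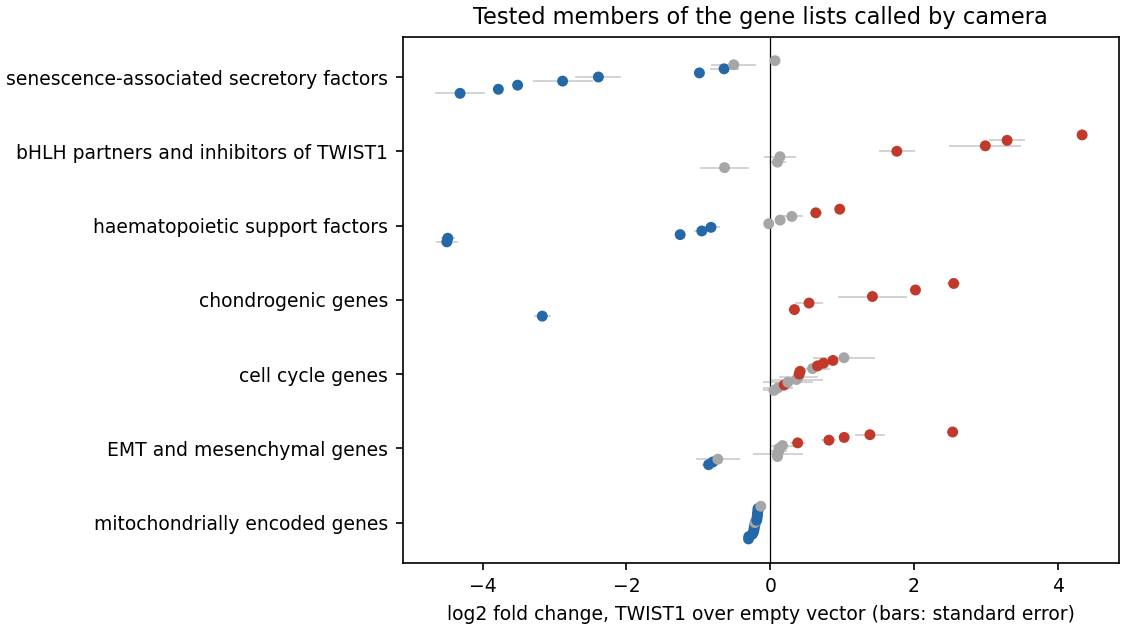
Log2 fold change with its standard error for the tested members of the 7 lists called by camera, red for members that rose, blue for those that fell and grey for those not called. None of the 7 list calls held with an estimated correlation, where the smallest adjusted p was 0.0539.

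Lineage genes moved in both directions. Chondrogenic genes were higher as a list (camera adjusted p = 0.00534, adjusted p = 0.203 with an estimated correlation), with 5 of 6 tested members rising and 1 falling, also when adjusted over the list alone. The other 14 of its 20 members had too few counts to be tested, among them the cartilage collagen gene COL2A1 with no count in any library. The cartilage matrix genes ACAN and FMOD rose from 42.1 ± 0.96 to 171 ± 15.9 CPM and from 14.1 ± 1.55 to 82.8 ± 1.77 CPM (SD, n = 3). The member that fell was SOX9, the transcription factor that directs cartilage formation, from 76.7 ± 1.54 to 8.51 ± 2.14 CPM (log2 fold change -3.17, SE 0.12, edgeR adjusted p = 6.08e-22). Of 10 tested osteogenic genes 3 rose, 2 fell and 5 were not called (camera adjusted p = 0.0772), and the list was called higher without TWIST1 replicate 1 (adjusted p = 0.0403). TNFRSF11B, the decoy receptor that restrains osteoclast formation, rose from 288 ± 7.18 to 1500 ± 62.9 CPM, OMD rose with a ratio of 112 (95% counting interval 19.6 to 4464), and the bone matrix gene IBSP fell from 12.6 ± 0.30 to 1.98 ± 0.42 CPM. The single OMD count in the empty-vector group lay in replicate 3, without which its fitted log2 fold change went from 6.33 to 8.14 (5.70 with limma-voom). BMP2 was not called (log2 fold change 0.76, edgeR adjusted p = 0.249). RUNX2, ALPL and FGFR2 had too few counts to be tested, at or below 0.646 CPM in both group means. Of 9 tested adipogenic genes 3 rose and 3 fell (camera adjusted p = 0.640), with LEP rising from 8.04 ± 1.00 to 65.0 ± 3.56 CPM and CD36 falling from 61.1 ± 5.46 to 11.8 ± 1.21 CPM. For CD36, 3.7% of counts lay on coding transcripts.

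Cell cycle genes were higher as a list (camera adjusted p = 0.00534, adjusted p = 0.176 with an estimated correlation). Of 13 tested members 6 rose and 0 fell, and 8 rose adjusted over the list alone. A further 15 of the 28 listed genes had too few counts to be tested. CCNA2, which drives S phase and entry into mitosis, rose from 114 ± 2.72 to 210 ± 8.39 CPM (SD, n = 3), CENPF from 253 ± 16.6 to 399 ± 3.46 CPM and the proliferation marker MKI67 from 11.2 ± 1.77 to 18.8 ± 1.24 CPM. Of 15 tested p53 targets and cyclin-dependent kinase inhibitors 5 rose and 4 fell (camera adjusted p = 0.859). CDKN2B fell from 34.5 ± 0.67 to 19.5 ± 4.47 CPM, and CDKN2C rose from 1.17 ± 0.20 to 2.90 ± 1.40 CPM, a call lost without TWIST1 replicate 3 (adjusted p = 0.168). CDKN2A, which encodes the p16 inhibitor of cell cycle entry, fell from 3.01 ± 0.09 to 1.63 ± 0.28 CPM (log2 fold change -0.88, SE 0.33, edgeR adjusted p = 0.0440). That call was lost on leaving out any one of the 6 libraries, with adjusted p between 0.0552 and 0.135. It was also lost with DESeq2 (0.134), no filter on low counts (0.104), the replicate number as a block (0.0585) and coding transcripts only (0.0634). CDKN1A and the Polycomb methyltransferase EZH2 had too few counts to be tested, at 1.30 ± 0.58 against 0.671 ± 0.291 CPM and at 0.583 ± 0.435 against 0.474 ± 0.146 CPM. Of their few counts 38.2% and 0% lay on coding transcripts, so low expression and uncounted reads cannot be told apart for these genes. Of 13 tested Polycomb and H3K27 demethylase genes 2 rose, CBX2 and CBX7 (camera adjusted p = 0.672). The receptor tyrosine kinase gene ROS1 had 0 counts in all 6 libraries.

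Mitochondrially encoded transcripts took 8.38% to 8.78% of counts in the TWIST1 libraries and 9.57% to 10.62% in the empty-vector libraries. As a list they were lower (camera adjusted p = 0.0206, adjusted p = 0.736 with an estimated correlation), with 13 of 15 members falling and all 15 adjusted over the list alone. The changes were small, with a median log2 fold change of -0.21, and the largest was of MT-RNR1 (log2 fold change -0.30, SE 0.04). The list call was lost without TWIST1 replicate 2 (adjusted p = 0.0525). Of 24 tested nuclear oxidative phosphorylation genes 3 fell and 1 rose, and of 28 cytosolic ribosomal protein genes 2 fell and 1 rose (camera adjusted p = 0.789 and 0.922). Of 6 replication-dependent histone genes 3 fell and 0 rose (camera adjusted p = 0.599).

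Signalling, matrix and metabolic lists held called genes without a list call. Of 25 tested collagens and matrix glycoproteins 8 rose and 8 fell (camera adjusted p = 0.109), with COL12A1 rising from 105 ± 2.55 to 439 ± 21.5 CPM and COL6A3 falling from 21.1 ± 5.57 to 3.86 ± 0.30 CPM (SD, n = 3). The median and mean of this list differed in sign (-0.03 and 0.18). In the FGF pathway list 4 rose and 7 fell of 12 (camera adjusted p = 0.859), with the phosphatase genes DUSP4 and DUSP6 falling (log2 fold changes -2.84 and -1.94) and SPRY1, a feedback inhibitor of receptor tyrosine kinase signalling, rising (2.02, SE 0.44). In the WNT list 3 rose and 5 fell of 12 (camera adjusted p = 0.109), where WNT2 had no count in empty-vector libraries and was at least 36.6-fold higher, and DKK2 fell (log2 fold change -3.09). In the BMP and TGF-beta list 5 rose and 4 fell of 18 (camera adjusted p = 0.973), with TGFBR2 falling (log2 fold change -1.88) and FST and SMAD6 rising (1.68 each). The call of SMAD6 was lost without TWIST1 replicate 2 (adjusted p = 0.0630). That of FST was lost with the replicate number as a block (adjusted p = 0.0607), and its log2 fold change was 2.355 without empty-vector replicate 3. In the Notch list 2 rose and 2 fell of 7 (camera adjusted p = 0.332), with HEYL falling (log2 fold change -1.40) and DLL1 rising (1.01). The call of DLL1 was lost without TWIST1 replicate 2 (adjusted p = 0.0976) and without empty-vector replicate 1 (adjusted p = 0.0517). Interferon-stimulated genes included 5 of 12 that fell and 0 that rose (camera adjusted p = 0.109), with IFIT2 falling from 76.5 ± 1.74 to 33.1 ± 2.76 CPM and IFI44L at least 12.9-fold lower. Of 22 glycolysis and hypoxia genes 8 fell and 1 rose (camera adjusted p = 0.0984), with PFKFB4 falling from 78.1 ± 4.38 to 39.0 ± 3.85 CPM, VEGFA from 75.8 ± 9.84 to 48.8 ± 0.82 CPM, and NDRG1 rising from 3.86 ± 0.69 to 6.93 ± 0.19 CPM. Without empty-vector replicate 1 the WNT, interferon and glycolysis lists were called lower (adjusted p = 0.0398, 0.0435 and 0.0492). With no filter on low counts the interferon and glycolysis lists were called lower (adjusted p = 0.0196 and 0.0181) and the collagen list higher (adjusted p = 0.0421), and with limma-voom the glycolysis list lower (adjusted p = 0.0104).

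Stromal surface markers showed 7 of 16 members rising and 4 falling (camera adjusted p = 0.442), with the neprilysin gene MME rising from 5.49 ± 0.65 to 67.6 ± 1.43 CPM (SD, n = 3) and the intermediate filament gene NES falling from 273 ± 7.75 to 88.4 ± 4.62 CPM. Of 12 smooth muscle contractile genes 2 rose and 2 fell (camera adjusted p = 0.640), with the coactivator gene MYOCD falling (log2 fold change -1.44) and LMOD1 rising (0.24). Immediate early and heat shock genes had 4 of 11 rising and 2 falling (camera adjusted p = 0.789), with NR4A1 rising (log2 fold change 2.62, SE 0.44, and 3.45 with coding transcripts only, which held 57% of its counts), EGR3 falling (-1.85, SE 0.18) and FOS rising (1.39, SE 0.44). The call of FOS was lost without TWIST1 replicate 3 (adjusted p = 0.0734) and without empty-vector replicate 1 (adjusted p = 0.106). Of 16 unfolded protein response genes 3 rose and 1 fell, and of 12 cholesterol synthesis genes 2 rose and 2 fell (camera adjusted p = 0.734 and 0.973). Of the haematopoietic cell markers 1 of 20 had enough counts to be tested, CD34 at 1.15 ± 0.38 against 1.13 ± 0.38 CPM. Of the endothelial markers 2 were tested, and TEK fell from 19.6 ± 3.00 to 6.41 ± 1.09 CPM.

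Reads that fit several isoforms of a gene appear not to have been counted, which limits the levels above. Fewer than 50% of counts lay on coding transcripts for 221 of 2439 called protein-coding genes, and for such genes, among them VEGFA, CD36, COL6A3, SPRY1, NDRG1, KRT18 and CDH11, the value describes the countable part of the gene only.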

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

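The test of transcripts without a gene name and the test with a GC trend removed were chosen after the main result was seen, and the tests of depth, GC content, length and isoforms before it. Outside the tested genes, 477 of the 23081 transcripts without a match had enough counts to be tested beside the genes, and 47 of them were higher and 55 lower with TWIST1 (edgeR adjusted p below 0.05). This is a signal in data that the comparison of genes did not use. Transcripts above 5 CPM with the largest changes were ENST00000464767 (log2 fold change 1.85, SE 0.16) and ENST00000318578 (1.31, SE 0.17) among those that rose, and ENST00000607314 (-3.57, SE 0.09) and ENST00000312932 (-2.53, SE 0.17) among those that fell. No gene was assigned to them.

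The 2898 called genes are the first pattern weighed. The real grouping was 1 of 10 splits of the 6 libraries into 3 and 3, too few for a share under 0.05, and the highest count of any other split was 0. With every library thinned to the shallowest depth, 2830 genes were called, 2731 of them also called at full depth, and the Spearman correlation of the log2 fold change with transcript length across tested genes was -0.065, which argues against depth and length as the cause. The Spearman correlation with GC content across genes was 0.153, between the bounds set in advance for a GC effect and for none, so a partial GC effect cannot be excluded. With a smooth GC trend removed from each library, that correlation was -0.037 and 2581 of the calls (89.1%) were kept in their direction, which argues against GC content as the whole cause, and an effect of TWIST1 or of any unrecorded difference between the groups stays open.

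The second pattern is the 221 called protein-coding genes counted mostly on non-coding transcripts, whose change may be one of isoform use. Over 171 genes with called non-coding transcripts and tested coding transcripts, the coding transcripts went the same way in 89.5% (95% interval 83.9% to 93.6%), above the bound set in advance against isoform change. Of the 221 genes themselves 43 (19.5%) could be tested so, and 41 of these went the same way. For the other members isoform change and a change of the gene cannot be told apart, because their coding transcripts had too few counts. In 3 of the 171 genes, WWC3, SUB1 and ANTXR1, both kinds were called in opposite directions.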

How the results depend on the processing

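Coding transcripts only and the set without mitochondrially encoded genes were chosen after seeing the data. The 4 counts of called genes stayed within 1.5 times of the main counts under every alternative run. Between 1043 (DESeq2) and 1342 genes were higher and between 1310 (DESeq2) and 1650 lower, and with 1 library left out 1075 to 1366 and 1384 to 1594. The log2 fold change of TWIST1 stayed between 5.10 and 5.23. No main call changed sign except 2 with coding transcripts only. The number of lists past the threshold was 7, and it was 0 with an estimated correlation, 19 with fry, which does not compare a list with other genes, and 6 to 10 with 1 library left out.

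Same-numbered libraries did not deviate together (correlations across genes of -0.08, 0.019 and -0.072), and none correlated best with its own number. No pairing by number was seen, but these correlations cannot exclude a shared donor, culture or transduction. With the number as a block 1115 genes were higher and 1471 lower. The filter meant to be stricter tested more genes, 11438, than the default.

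Of 97 called named genes besides TWIST1, 82 kept their call in every alternative that tested them and 15 lost it in at least 1. Among those reported here, the highest adjusted p over all alternatives was 0.315 for CHAC1, 0.177 for RPS19, 0.176 for CALR, 0.168 for CDKN2C, 0.135 for CDKN2A, 0.134 for RPL23, 0.122 for H2BC4, 0.106 for FOS, 0.0976 for DLL1, 0.0762 for RPL37A, 0.0630 for SMAD6, 0.0607 for FST with the replicate number as a block, 0.0605 for DNAJB9 and 0.0561 for NDUFS1. Of the called lists, the haematopoietic support factors were lost with limma-voom (adjusted p = 0.238) and the mitochondrially encoded genes with coding transcripts only (0.061) and without TWIST1 replicate 2 (0.0525). With fry set aside, 5 lists that were not called passed the threshold in at least 1 alternative. Among the named genes and the lists, the sign turned only for results that were not called, and the cause was not tested. The BMP and TGF-beta list turned with fry (adjusted p = 0.833), limma-voom (0.836), no filter (0.849) and without empty-vector replicate 2 (0.824), and spanned 0.824 to 0.994 with 1 library left out. The cholesterol list turned with no filter (0.728), without TWIST1 replicate 3 (0.926) and without empty-vector replicates 2 (0.959) and 3 (0.984), and spanned 0.926 to 0.986. CD34 had a log2 fold change of -0.21 with coding transcripts only, -0.27 without TWIST1 replicate 2 and -0.19 without empty-vector replicate 2, and spanned -0.27 to 0.27. RUNX2, ALPL, EZH2, SNAI2, CDKN1A and FGFR2 had too few counts to be tested. Whether low expression, depth or uncounted reads shared between isoforms set this was not tested.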

Other observations

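Except for the BMP and TGF-beta pathway list, all gene lists in this part were drawn up after the data had been seen, so their tests were chosen after the result. There were 8 such lists, 7 of them large enough for camera, and p-values are given raw and adjusted over those 7, and only adjusted for the test with an estimated correlation. With an estimated correlation the calls of the integrin, MAPK output and BMP-SMAD target lists were lost. Small leucine-rich proteoglycans, which bind collagen fibrils, rose in 7 of 9 tested members and fell in 1 (camera p = 3.07e-11, adjusted p = 2.15e-10, adjusted p = 0.0337 with an estimated correlation). PRELP rose from 10.5 ± 1.56 to 149 ± 7.18 CPM (SD, n = 3) and LUM from 72.2 ± 1.74 to 114 ± 9.41 CPM, while DCN fell (log2 fold change -0.45, SE 0.15). Integrin genes fell in 5 of 12 tested members and rose in 2 (camera p = 0.00861, adjusted p = 0.0121, adjusted p = 0.0891 with an estimated correlation). ITGA2, a collagen receptor subunit, fell from 176 ± 2.14 to 14.0 ± 1.13 CPM and ITGA8 rose from 300 ± 15.5 to 1502 ± 39.1 CPM. The list of BMP and GDF ligands also held INHBA, which encodes an activin subunit and is neither a BMP nor a GDF. This list fell in 3 of 12 tested members and rose in 1 (camera p = 5.04e-05, adjusted p = 0.000118, adjusted p = 0.0443 with an estimated correlation). INHBA fell from 2793 ± 50.4 to 1359 ± 22.1 CPM. Of 19 tested HOX genes 3 rose and 2 fell, with a camera adjusted p = 0.77, as before adjustment.

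EGF-family ligands fell in 5 of 6 tested members (camera p = 1.07e-10, adjusted p = 3.74e-10, adjusted p = 0.0189 with an estimated correlation), with log2 fold changes of -4.47 for TGFA, -3.72 for NRG1 and -3.33 for EPGN. MAPK output genes, which ERK signalling induces, fell in 6 of 8 and rose in 1, SPRY2 (camera p = 0.00543, adjusted p = 0.0095, adjusted p = 0.0791 with an estimated correlation). SPRY1 and the immediate early genes NR4A1 and FOS, all outside that list, rose, while EGR3 fell. The call of FOS was lost without TWIST1 replicate 3 (edgeR adjusted p = 0.0734) and without empty-vector replicate 1 (0.106). A candidate explanation is lower ERK output, but the MAPK output genes are part of the pattern and were picked after their values were seen. Their fall therefore does not test it, and ERK activity was not measured. Fewer admixed epithelial cells are the technical candidate, and the median of 6 epithelial genes in empty-vector libraries was 0.501 CPM. This lay between the bounds of 0.5 and 1 CPM, which were set after the data had been seen. The epithelial genes KRT14 (102 ± 10.7 to 147 ± 6.87 CPM) and DSP (581 ± 21.0 to 777 ± 17.6 CPM) rose, while CLDN1, KRT18 and KRT19 fell (log2 fold changes -5.32, -1.75 and -0.52) and EPCAM and KRT5 had no counts, so neither explanation is settled.

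As a hypothesis, the rise of ID1 to ID4 may reflect higher BMP-SMAD activity, since ID genes are direct targets of that pathway. Of 7 tested BMP-SMAD targets other than the ID genes 4 rose and 0 fell (camera p = 0.0106, adjusted p = 0.0124, adjusted p = 0.0813 with an estimated correlation), but this list was drawn up after the values were seen, so it does not test the hypothesis. In the BMP and TGF-beta list fixed in advance 5 of 18 rose and 4 fell (camera adjusted p = 0.973). ATOH8 rose from 18.3 ± 1.51 to 77.3 ± 12.2 CPM (SD, n = 3), and the call of SMAD6 was lost without TWIST1 replicate 2 (adjusted p = 0.0630). SMAD7, BAMBI and NOG were not called, and the ligand genes GDF5 and GDF6 fell, so higher BMP-SMAD activity and induction of the ID genes without it both stay open.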
